A study of Rattus norvegicus with 6 samples.

How the data were processed

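RNA sequencing of rat kidney compared contrast-induced acute kidney injury (CI-AKI) with control, with 3 libraries in each group. Per the labels, male Sprague-Dawley rats of 3 months and about 250 g went without water for 48 hours and were then given INDO and L-NAME, each at 10 mg/kg and 15 minutes apart. INDO was read as indomethacin, which blocks prostaglandin synthesis. L-NAME blocks nitric oxide synthesis, and both drugs reduce vasodilation in the kidney. The rats were then randomized to an injection of 7.8 ml/kg of the iodinated contrast medium iopromide (CI-AKI) or of saline (control). Kidney was taken about 12 hours after the injection, and total RNA was sequenced. The control rats therefore received everything but the contrast medium. Each table column was tied to its library by the group and replicate number in its name, where Case was read as CI-AKI, the only group besides control.

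The authors deposited 1 table of 30957 Ensembl genes with a whole-number read count and an FPKM (fragments scaled to gene length and library total) for each gene and library. The submitters' processing notes name HISAT2 2.0.4, Cufflinks 2.1.1, Cuffdiff and the rat build rn6, without their roles. The program that counted the reads and its handling of reads shared between genes are not given in the sources used here. The deposited FPKM was checked against the counts. Over the 9130 genes with more than 200 counts in every library, it equalled the count divided by a gene length and the column total, with a largest relative difference in that length of 4.3e-06 between libraries. The FPKM columns therefore hold the same measurements as the counts. Coordinates are those of the table, counted from 1 and including both ends. Gene classes came from a reference table by symbol (16427 genes) or by an unambiguous synonym (2153 genes). The other 12377 genes had no match and no class, and 25 genes had the class lncRNA (long noncoding RNA).

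The main test was planned for FPKM, with a count test to take its place if the table gave counts, which it did. Counts were analysed with edgeR 4.0.16 under R 4.3.3. Genes were kept by the default expression filter (a minimum count of 10 scaled to library size and a total of at least 15), which left 14564 genes. Libraries were scaled by TMM, a trended dispersion was estimated, and edgeR's quasi-likelihood test compared CI-AKI with control two-sided, with group as the only term. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. Fold changes are log2 of CI-AKI over control with their standard error (SE). Levels are CPM, counts scaled to a common library total with the TMM factors, as mean ± SD over 3 libraries.

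The design, the groups, the alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. The lists cover tubule segments, other kidney and blood cell types, and injury, stress, metabolic and clock pathways, and some genes stand in more than 1 list. The 32 lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The adrenal list, with 3 tested genes, was not tested. Camera with an estimated correlation and fry were alternatives. Camera asks whether the genes of a list move relative to all other genes, while fry asks whether they move on balance in 1 direction or, in its mixed form, in either direction.

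The rule named 10 genes in each direction with a mean CPM of at least 1, a standard symbol and groups that did not overlap. It also named Havcr1, Lcn2, Clu, Spp1 and Timp1, up to 4 genes of each list by smallest p, up to 4 lncRNA genes in each direction and the 5 genes with the smallest p. Since fewer than 5 genes passed the threshold, the 10 in each direction and the lncRNA genes were taken by smallest p, and none of them passed. Genes named beyond the rule are members of the fixed lists or are said to have been chosen after their values were seen.

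Alternatives were DESeq2 1.42.0, limma on log2(FPKM + 0.1, 0.5 or 1) for genes with a mean FPKM of at least 0.5, median-of-ratios size factors, no scaling beyond library size, quantile normalization, no filter on low counts, a mean count of at least 10, no abundance trend, a robust spread estimate (for genes, since camera has no such option), library weights with limma's voom, a block for the replicate number, and each library left out in turn. When 1 library of a group is left out, the model estimates the spread from the remaining 5. On simulated counts with 200 changed genes among 14564 and the dispersion trend of these libraries, the main test recovered 66% of 2-fold and 96.9% of 4-fold changes with 4 false calls. The simulation gave every gene the trended dispersion, so these shares are upper estimates for real genes. Library totals ran from 20094729 to 23058144 counts, so that 3 counts, the limit that a count of 0 allows, correspond to at most 0.149 CPM, for counting error only. The labels do not tie the libraries to separate animals, so p-values measure only the spread between these libraries.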

Results

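The kidney transcriptome was measured 12 hours after injection of iodinated contrast medium or saline into rats sensitised by water deprivation, INDO (read as indomethacin) and L-NAME, with 3 CI-AKI and 3 control libraries. The libraries held 21615180, 20970665 and 20649311 counts in control replicates 1 to 3 and 23058144, 20181532 and 20094729 counts in CI-AKI replicates 1 to 3. Between 18460 and 18644 genes had a count in each library, and the 10 most abundant genes took 9.9% to 11.1% of the counts. Control libraries correlated with each other at 0.9823 to 0.9841 across genes (log2 CPM; genes are not independent replicates). CI-AKI replicates 1 and 2 correlated at 0.9886. CI-AKI replicate 3 correlated with them at 0.9623 and 0.9603, below its 0.9754 to 0.9782 with the controls. The first principal component held 46% of the variance and placed CI-AKI replicates 1 and 2 at 40.3 and 39.2, the controls from -19.9 to -6.9 and CI-AKI replicate 3 at -33.6. The second component held 20.5% and separated the groups. It placed control replicates 1 to 3 at 25.4, 9.3 and 11 and CI-AKI replicates 1 to 3 at -12.4, 2.2 and -35.5. No pair of libraries was close to sampling noise, since the lowest chi-square per degree of freedom was 15.8, between CI-AKI replicates 1 and 2.

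The first comparison asked which genes differ in the kidney after contrast medium. The clearest single difference was a lower level of Rasd2, which encodes a small GTPase of the Ras family, at 4.99 ± 0.723 CPM in CI-AKI against 20.09 ± 2.53 in control (SD, n = 3 each). The genes with the next smallest p in the direction of lower expression included Cmah, the hydroxylase that makes N-glycolylneuraminic acid, at 5.95 ± 0.309 against 12.4 ± 1.56 CPM, and Ppp1r1a, a protein phosphatase 1 inhibitor, at 60.5 ± 12.8 against 131 ± 16.4 CPM. In the other direction stood the DNA replication clamp Pcna, at 81.5 ± 17 against 44.5 ± 3.69 CPM, and the thymidine salvage enzyme Tk1, at 43.0 ± 8.35 against 22.1 ± 3.26 CPM. None of these passed the threshold over all genes. With all 6 libraries, edgeR's quasi-likelihood test called 0 of 14564 genes at an adjusted p under 0.05. The smallest adjusted p was 0.0837, for Rasd2, whose log2 change was -2.01 (SE 0.16). An unadjusted p under 0.05 was reached by 1949 genes, 1036 higher and 913 lower in CI-AKI, where chance would give 728. The groups did not overlap for 2780 genes, 19.1% of those tested, where chance gives 10% for 3 against 3. Both chance values are averages over groupings. Genes are not independent, so a single grouping can lie far from them, and no other split was counted this way. DESeq2 called 216 genes, 97 higher and 119 lower, and left 6488 without an adjusted p. For any single gene, an exact permutation of 3 against 3 libraries cannot give a p below 0.1.

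The count of genes rested on CI-AKI replicate 3. Without it, edgeR's quasi-likelihood test called 2324 of 14802 genes, 1259 higher and 1065 lower, of which 481 differed at least 2-fold. Leaving out any other single library gave 0 genes. Leaving out each library was planned, and this library was singled out only after the counts were seen. Of the 216 genes called by DESeq2 on all 6 libraries, 199 were among the 2324.

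**Figure D1:**
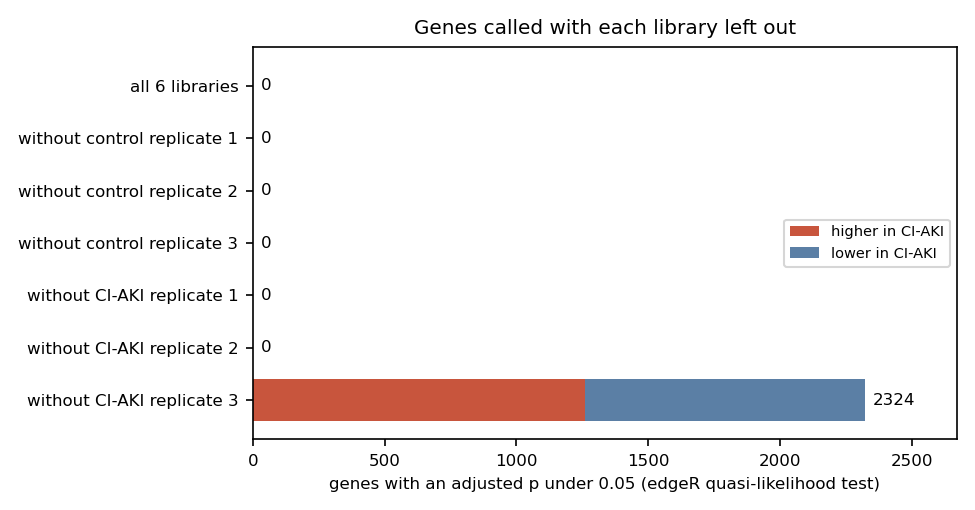
Bars give the number of genes (x axis) with an adjusted p under 0.05 in edgeR's quasi-likelihood test for all 6 libraries and with each library left out in turn, split by direction. Leaving out CI-AKI replicate 3 gave 2324 genes, and every other bar is at 0.

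Besides Pcna and Tk1, the 10 genes named in the direction of higher expression were Lrrcc1, Acot7, Thoc7, Cplx1, Hormad1, Kpna2, Exoc6 and Polb. Their log2 changes ran from 0.42 for Exoc6 to 1.37 for Cplx1. Lrrcc1, a centrosomal protein gene, stood at 45.9 ± 4.6 against 19.4 ± 4.63 CPM, a log2 change of 1.24 (SE 0.19). Kpna2, a nuclear import receptor gene, differed by 0.67 (SE 0.12), and Polb, the DNA polymerase of base excision repair, by 0.60 (SE 0.11). Besides Rasd2, Cmah and Ppp1r1a, the 10 named in the direction of lower expression were Efr3b, Ndrg4, Ugt8, Gng7, Cd200, Slc37a1 and Rassf10. Ndrg4 stood at 41.4 ± 3.48 against 80.0 ± 12.8 CPM. Gng7, a G protein gamma subunit gene, stood at 20.9 ± 4.97 against 47.9 ± 3.35 CPM, a log2 change of -1.20 (SE 0.18). All of these except Rasd2 had an adjusted p of 0.28 with all 6 libraries. When CI-AKI replicate 3 was left out, all 20 genes passed, with adjusted p from 0.006 for Rasd2 to 0.024 for Hormad1. These genes had been picked from the same libraries by smallest p and groups that did not overlap. Their passing is therefore no independent support. The 5 genes with the smallest p were Rasd2, Cmah, LOC100360679 (ribosomal protein S18-like), LOC100359600 (karyopherin alpha 2-like) and Mat1a. Mat1a, a methionine adenosyltransferase gene, was at 0.22 ± 0.03 CPM in control and 1.45 ± 0.46 in CI-AKI, a log2 change of 2.68 (SE 0.37). In the table's rn6 coordinates, Rasd2 lies on chromosome 19 (14653198 to 14663914), Ppp1r1a on chromosome 7 (145146481 to 145154131) and Pcna on chromosome 3 (124880698 to 124884570).

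Genes of the thick ascending limb, the segment that reabsorbs salt without water, were lower as a group in CI-AKI. All 12 tested genes had a lower mean, with a median log2 change of -0.32, and the list's median was -0.41, -0.43 and -0.37 in CI-AKI replicates 1 to 3 relative to the control mean. Slc12a1, the apical sodium, potassium and chloride cotransporter, stood at 1954 ± 282 against 3079 ± 193 CPM, a log2 change of -0.66 (SE 0.16). Umod, which encodes uromodulin, stood at 2031 ± 578 against 3509 ± 655 CPM. Camera gave the list an adjusted p of 2.33e-05, and adjusted p = 0.229 with an estimated correlation, while fry gave 0.0188. No gene of the list passed over all genes tested, and 2 passed when adjusted over the list alone. With CI-AKI replicate 3 left out, 6 of the 12 genes fell.

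Endothelial genes were also lower as a group, in 11 of 13 tested genes, with a median log2 change of -0.35. Tek, the angiopoietin receptor, stood at 115 ± 14 against 167 ± 10.5 CPM (log2 change -0.54, SE 0.11), and Vwf, which encodes von Willebrand factor, at 40.6 ± 5.17 against 59.8 ± 7.26 CPM (log2 change -0.56, SE 0.13). Cldn5, a tight junction gene, had a log2 change of -0.57 (SE 0.15). Nos3, endothelial nitric oxide synthase, stood apart from these, at 42.8 ± 17.5 against 31.8 ± 0.98 CPM. Camera gave an adjusted p of 0.000908, and adjusted p = 0.229 with an estimated correlation. Adjusted over the list alone, Tek, Vwf and Cldn5 passed, and over all genes tested no gene did. With CI-AKI replicate 3 left out, 7 genes of the list fell and Nos3 rose (log2 change 0.72, SE 0.11).

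Lymphocyte genes were lower in all 7 tested members, with a median log2 change of -0.72. Cd4 stood at 14 ± 4.1 against 22.7 ± 2.34 CPM, and the T cell kinase gene Lck at 1.51 ± 0.54 against 2.85 ± 0.33 CPM. Cd4 was thus far above the other named members, such as Cd3e at 1.3 CPM in control, and which cells it came from was not tested. Cd3e and Cd79a rested on few counts, 5 to 41 and 6 to 22 per library. Camera gave an adjusted p of 0.00316, and adjusted p = 0.956 with an estimated correlation, and no gene passed when adjusted over the list alone. The list's median was -0.95 and -1.15 in CI-AKI replicates 1 and 2 and -0.20 in replicate 3, close to the -0.23 of control replicate 3. The median was -1.24 when that library was left out. Macrophage genes had a median of -0.12 (adjusted p 0.657) and neutrophil genes 0.17 (0.878). The neutrophil median was 0.51 without CI-AKI replicate 3 and -0.06 without CI-AKI replicate 2, and neither was called.

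Cell cycle genes were higher as a group, with a median log2 change of 1.07 in 17 tested genes, of which 16 had a higher mean. Pcna, Tk1 and the replicative helicase gene Mcm2 were higher than every control in all 3 CI-AKI libraries, and these 3 passed when adjusted over the list alone. Mcm2 stood at 61.7, 43.0 and 52.5 CPM in CI-AKI against 22.2, 28.6 and 34.6 in control. Top2a and Mki67 were chosen after their values were seen. Top2a, DNA topoisomerase II alpha, reached 52.7 CPM in CI-AKI replicate 3 against 3.17 and 2.45 in CI-AKI replicates 1 and 2 and 3.02 to 13.4 in control. Mki67, the proliferation marker Ki-67, reached 59.8 CPM there against 9.11 and 3.79 in CI-AKI replicates 1 and 2 and 4.74 to 15.7 in control. Camera gave the list an adjusted p of 0.000908, and adjusted p = 0.956 with an estimated correlation. When that library was left out, the list's median was 0.25 and its adjusted p was 0.509, and with library weights they were 0.10 and 0.267.

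Genes of cholesterol synthesis were higher as a group, in 15 of 16 tested genes, with a median log2 change of 0.27. The squalene epoxidase gene Sqle stood at 57.3 ± 13.7 against 33.3 ± 7.46 CPM (log2 change 0.79, SE 0.22). The lanosterol demethylase gene Cyp51 stood at 50.5 ± 3.79 against 36.1 ± 4.87 CPM (log2 change 0.49, SE 0.12). Camera gave an adjusted p of 0.000908, and adjusted p = 0.856 with an estimated correlation. No gene passed over all genes tested or when adjusted over the list alone, and without CI-AKI replicate 3 the adjusted p of the list was 0.152, and with library weights it was 0.0571. Erythroid genes were higher in all 6 tested members, with a median log2 change of 0.45, and the alpha globin gene Hba1 stood at 313 ± 88.3 against 196 ± 43.9 CPM. Their adjusted p was 0.0158, and adjusted p = 0.956 with an estimated correlation. This call was lost without control replicate 1 (median 0.25, adjusted p 0.119), without CI-AKI replicate 2 (median 0.33, adjusted p 0.0589) and without CI-AKI replicate 3 (median 0.55, adjusted p 0.0571), and over all libraries left out in turn the adjusted p ran from 0.00115 to 0.119.

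**Figure D2:**
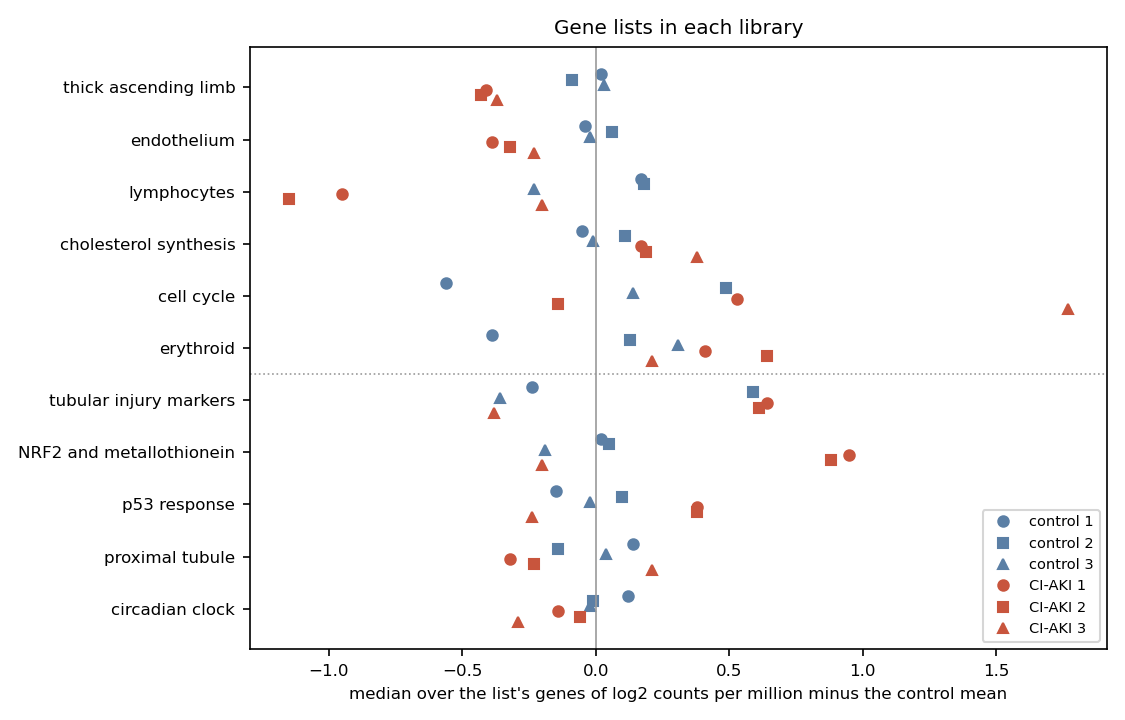
Each point is the median over a list's genes (x axis: log2 CPM minus the control mean) in 1 library, with controls in blue and CI-AKI in red. The lists above the dotted line were called by camera. The 3 CI-AKI libraries lie at -0.41, -0.43 and -0.37 for thick ascending limb genes, while CI-AKI replicate 3 lies apart from the other CI-AKI libraries at 1.77 for cell cycle genes and at -0.20 for NRF2 and metallothionein genes.

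Markers of tubular injury did not separate the groups. Havcr1, which encodes kidney injury molecule 1, was highest in control replicate 2, at 156 CPM, against 25.3 and 14.5 in the other controls and 41.6, 42.2 and 17.0 in CI-AKI. Lcn2, which encodes neutrophil gelatinase-associated lipocalin, stood at 195, 161 and 20.4 CPM in CI-AKI and 63.9, 146 and 47.5 in control. Clu had a log2 change of -0.71 (SE 0.34), Spp1 of -0.53 (SE 0.42) and Timp1 of 0.40 (SE 0.51). In edgeR's quasi-likelihood test the adjusted p of these 5 genes ran from 0.40 to 0.75. The list of 22 injury markers had a median log2 change of 0.34 and an adjusted p of 0.477. Its median was 0.64 and 0.61 in CI-AKI replicates 1 and 2 and -0.38 in replicate 3, while in control it was -0.24, 0.59 and -0.36. Leaving out any library other than CI-AKI replicate 3 or control replicate 2 gave this list a median of 0.12 to 0.21 and no call. The list was called higher without CI-AKI replicate 3 (median 0.55, adjusted p 0.0342) and without control replicate 2 (median 0.62, adjusted p 0.00752). These calls were lost, with adjusted p = 0.814 and adjusted p = 0.882 with an estimated correlation.

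The NRF2 targets Nqo1 and Prdx1, the metallothionein gene Mt1 and the p53 targets Ccng1 and Bax were higher in CI-AKI replicates 1 and 2 than in every control. Nqo1, which reduces quinones, stood at 111 and 103 CPM in replicates 1 and 2, at 13.1 in replicate 3 and at 22.2 to 38.2 in control. The NRF2 and metallothionein list had a median log2 change of 0.65 and an adjusted p of 0.257 with all libraries. With any library other than CI-AKI replicate 3 left out, its median ran from 0.27 (without CI-AKI replicate 1) to 0.70 (without control replicate 2), with no call. Leaving out CI-AKI replicate 3 gave a median of 0.92 and an adjusted p of 0.0178, but adjusted p = 0.789 with an estimated correlation, and 4 of 13 genes rose, among them Nqo1, Prdx1 and Mt1, while 1 fell. The p53 list had a median of 0.10 and an adjusted p of 0.477 with all libraries. Leaving it out gave a median of 0.25 and an adjusted p of 0.0481, but adjusted p = 0.789 with an estimated correlation, and 5 of 16 genes rose, among them the cyclin gene Ccng1 and the cell death effector gene Bax.

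Genes of the proximal tubule had a median of -0.32 and -0.23 in CI-AKI replicates 1 and 2 relative to the control mean. The median was 0.21 in CI-AKI replicate 3 and 0.14, -0.14 and 0.04 in control replicates 1 to 3. Slc34a1, the sodium and phosphate cotransporter of that segment, stood at 1090 and 990 CPM in CI-AKI replicates 1 and 2, at 3470 in replicate 3 and at 2390 to 3440 in control. With all libraries the list of 24 genes had a median log2 change of 0.01 and an adjusted p of 0.923. With CI-AKI replicate 3 left out, 7 of its genes fell and 1 rose, with a median of -0.31 and an adjusted p of 0.0749 for the list. The genes that fell included Slc34a1 (log2 change -1.57, SE 0.19), the endocytic receptor gene Lrp2 (-0.71, SE 0.13) and the inositol oxygenase gene Miox (-1.12, SE 0.22), while G6pc, the catalytic subunit of glucose-6-phosphatase, rose (0.61, SE 0.12). With all libraries, 12 of the 24 genes had a higher mean and 12 a lower one. Ahead of Slc34a1 by p stood Kap (913 ± 470 against 437 ± 103 CPM), Slc5a12 (394 ± 41.2 against 310 ± 34.2 CPM) and Slc17a3 (379 ± 53.3 against 304 ± 32.1 CPM), all higher in CI-AKI. Without CI-AKI replicate 3 their log2 changes were 0.57, 0.41 and 0.41, and none passed. The respiratory chain list had a median of -0.14 (adjusted p 0.125), and it was called lower without CI-AKI replicate 3 (median -0.22, adjusted p 0.0173) and without control replicate 2 (median -0.19, adjusted p 0.0136). These calls were lost, with adjusted p = 0.789 and adjusted p = 0.882 with an estimated correlation.

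**Figure D3:**
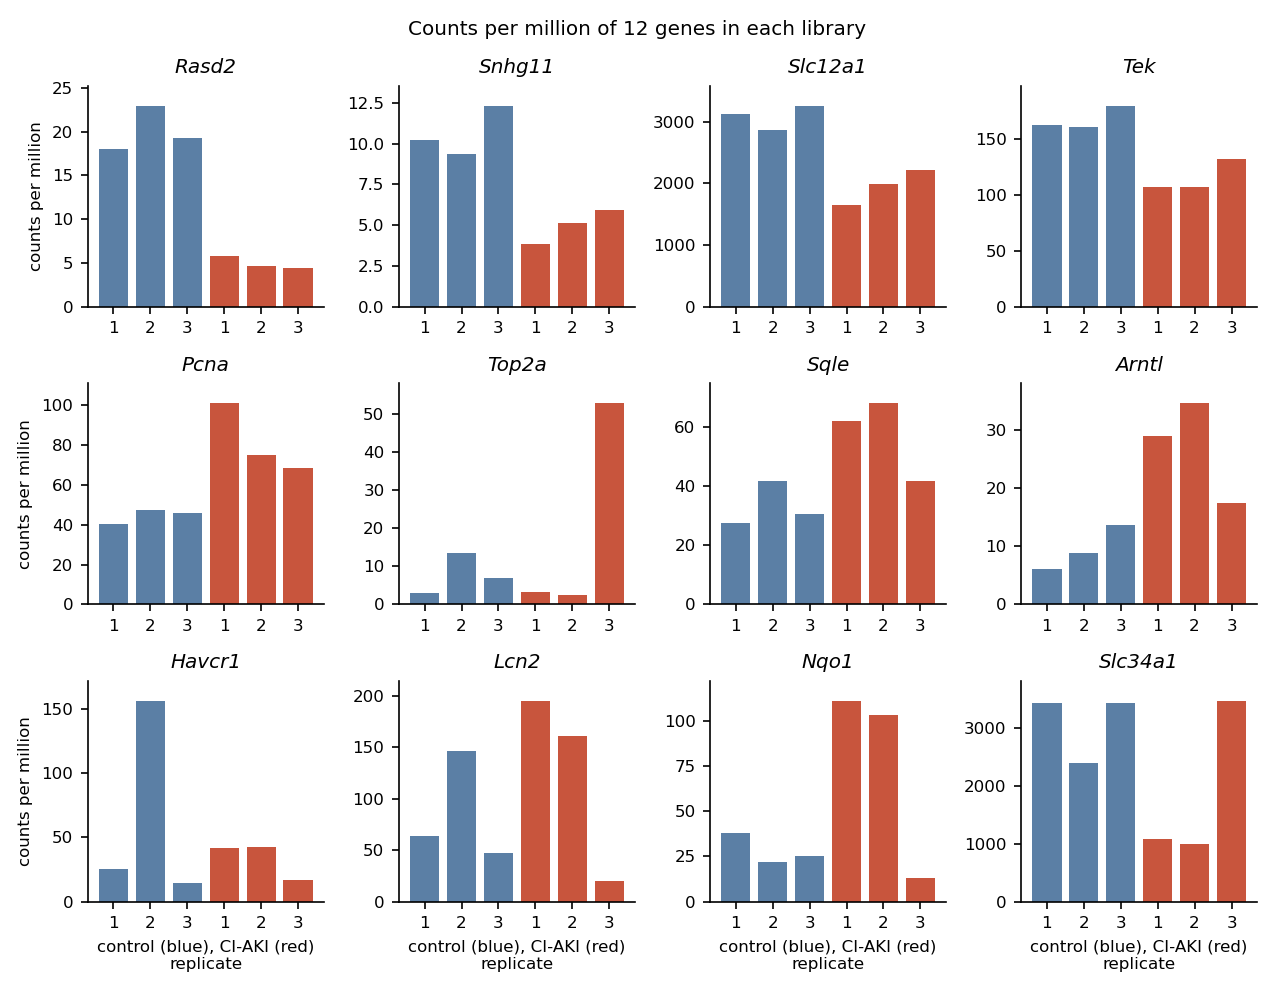
Bars give the level in CPM (y axis) of 12 genes in control (blue) and CI-AKI (red) replicates 1 to 3. Rasd2, Snhg11, Slc12a1, Tek, Pcna, Sqle and Arntl separate the groups in all 6 libraries, while Nqo1 and Slc34a1 set CI-AKI replicates 1 and 2 apart from replicate 3 and from the controls, and Top2a is high in CI-AKI replicate 3, at 52.7 CPM.

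The other nephron and glomerular lists were not called by camera in the main test, while fry called the medullary osmolyte and urea transport list lower. Medullary osmolyte and urea transport genes had a median log2 change of -0.27 (adjusted p 0.125, fry 0.0394), podocyte genes -0.19 (0.109), collecting duct principal cell genes -0.15 (0.236) and intercalated cell genes -0.14 (0.477). These 4 lists were called lower without control replicate 1, with medians of -0.27, -0.28, -0.28 and -0.30 and adjusted p of 0.0356, 0.00821, 0.00872 and 0.0144. Over the other libraries left out in turn, the medians came as close to 0 as -0.03 for principal cells (without control replicate 2 or 3), -0.02 for intercalated cells (without control replicate 2) and -0.09 for podocytes (without control replicate 3). With an estimated correlation none of these calls held (adjusted p = 0.803 for the first and adjusted p = 0.924 for the others, with an estimated correlation). Within the medullary list, Nfat5, the tonicity-responsive transcription factor, stood at 338 ± 12.8 against 445 ± 32.2 CPM, and the urate transporter gene Slc2a9 at 38.4 ± 3.23 against 26.5 ± 1.36 CPM. These 2 genes passed when adjusted over the list alone. Distal convoluted and connecting tubule genes had a median of 0.03 (adjusted p 0.923), where the thiazide-sensitive cotransporter gene Slc12a3 stood at 639 ± 55.7 against 492 ± 44.7 CPM.

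Genes of the circadian clock differed in opposite directions. Arntl, which encodes the activator BMAL1, stood at 27.1 ± 8.76 CPM in CI-AKI against 9.52 ± 3.82 in control, a log2 change of 1.51 (SE 0.35), and its partner gene Npas2 at 4.69 ± 0.92 against 2.78 ± 0.11 CPM. Tef, a clock output transcription factor, stood at 134 ± 31.1 against 226 ± 38.4 CPM, a log2 change of -0.76 (SE 0.19). These 3 genes passed when adjusted over the list alone, and none of the 16 passed over all genes tested. The list had a median of -0.13 and an adjusted p of 0.477.

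The remaining lists were not called by camera in the main test, and some of their medians near 0 changed sign with 1 library left out. Among signalling and stress lists, the median log2 change was 0.08 for immediate early genes (adjusted p 0.657), 0.12 for inflammatory cytokine genes (0.652), 0.10 for interferon genes (0.929), 0.02 for hypoxia genes (0.657), 0.11 for cell death genes (0.652) and 0.08 for TGF-beta and matrix genes (0.524). The immediate early median ran from -0.20 without control replicate 1 to 0.39 without control replicate 2, with no call. For glucocorticoid response genes it was 0.00 (0.456), and this list was called lower without CI-AKI replicate 2 (median -0.34, adjusted p 0.0147, but adjusted p = 0.953 with an estimated correlation). Adipose genes had a median of 0.00 (0.657), vasoactive genes 0.03 (0.923) and fibroblast and mural cell genes 0.05 (0.477). The last was called higher without control replicate 3 (median 0.16, adjusted p 0.0437, but adjusted p = 0.789 with an estimated correlation), and its member Dcn, which encodes decorin, stood at 104 ± 2.1 against 63.4 ± 13 CPM. Unfolded protein response genes had a median of -0.05 (0.923), heat shock genes -0.01 (0.923) and fatty acid oxidation genes -0.03 (0.957), where camera and the mean pointed the other way. The proximal tubule and vasoactive lists also had a median and mean above 0 while camera pointed lower. Herpud1, a gene of protein degradation at the endoplasmic reticulum, stood at 190 ± 1.61 against 269 ± 24.8 CPM and passed when adjusted over the list alone, as did Klf9 of the glucocorticoid list, Psmb8 of the interferon list and Dcn of the fibroblast list. The 3 tested adrenal genes, with a median of 0.27, were too few for a test.

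With the preset correlation, camera thus called 3 lists higher and 3 lower of 32 and left 26 with adjusted p from 0.109 to 0.957. Each other split of the 6 libraries into 3 and 3 also called at least 6 lists, so this number does not set the real grouping apart. With an estimated correlation camera called none in the real grouping, with a smallest adjusted p of 0.229.

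The second comparison concerned long noncoding RNAs, which the study set out to profile beside mRNAs. Among the 8 tested genes with the class lncRNA, the clearest difference was that of Snhg11, a small nucleolar RNA host gene on chromosome 3 (154863072 to 154869460). It stood at 4.99 ± 1.05 CPM in CI-AKI against 10.6 ± 1.5 in control, a log2 change of -1.09 (SE 0.20), and was lower in each CI-AKI library than in every control. Only 8 genes with the class lncRNA passed the expression filter, so this comparison covers few of them. A further 1493 tested genes had no class and may include noncoding genes. Of these, edgeR called 0 with all 6 libraries, and without CI-AKI replicate 3 it called 156 of 1560 such genes. In edgeR's quasi-likelihood test, 0 of the 8 passed over all genes tested, where Snhg11 had an adjusted p of 0.276, and 1, Snhg11, passed when adjusted over the list alone. It was also the 1 lncRNA gene with an unadjusted p under 0.05 and the 1 called by DESeq2 (adjusted p 0.0018) and without CI-AKI replicate 3 (adjusted p 0.014, edgeR). Several of the other genes carry names of receptor or histocompatibility genes, and their class is that of the reference table. LOC102548818, RT1-CE6 and LOC102549726 had higher means, with log2 changes of 1.04, 1.30 and 0.35. Ncr2, RT1-T24-2 and LOC102548225 had lower means, with log2 changes of -0.39, -0.24 and -0.21. The adjusted p of these 6 genes ran from 0.41 to 0.77.

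The third comparison took the protein-coding genes alone. Here too Rasd2 led, and the higher and lower genes with an unadjusted p under 0.05 numbered 928 and 841. Slc12a1, Tek and Pcna, described with their lists, are among these genes. With all 6 libraries, edgeR's quasi-likelihood test called 0 of 13016 protein-coding genes over all genes tested, and 0 when adjusted over the list alone, while 1769 had an unadjusted p under 0.05. DESeq2 called 199, 88 higher and 111 lower. Leaving out CI-AKI replicate 3, edgeR called 2161 of 13184, 1161 higher and 1000 lower.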

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

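The tests chosen only after the result was seen are the 3 that leave out CI-AKI replicate 3 together with another scaling or DESeq2. The count of 0 genes was the same in every alternative that kept all 6 libraries with equal weight and used edgeR or limma, including the FPKM fits, both filters and the replicate block. Library weights, which gave CI-AKI replicate 3 a weight of 0.23, called 2070 genes, 1 lncRNA gene and 1901 protein-coding genes, and DESeq2 called 216, 1 and 199. At an adjusted p under 0.1 the count was 1, and at an unadjusted p under 0.05 it was 1949. Leaving out 1 library gave 0 to 2324 genes, 0 to 1 lncRNA genes and 0 to 2161 protein-coding genes, where the highest came without CI-AKI replicate 3 and every other library left out gave 0. In those 3 tests, chosen after seeing the data, the counts for all genes, lncRNA genes and protein-coding genes were 2322, 1 and 2160 with median-of-ratios size factors, 2316, 1 and 2156 without scaling beyond library size, and 3041, 1 and 2838 with DESeq2. Of the 2070 weighted calls, 1855 were among the 2324. The robust spread estimate was not run for lists, since camera has no such option. The gene lists called numbered 8 with library weights, 6 to 9 when 1 library was left out, 0 with an estimated correlation and 3 with fry. The 8 lists, 3 higher and 5 lower, included some outside the 6 called in the main test. The 3 of fry included the medullary osmolyte and urea transport list. With an estimated correlation no adjusted p passed, and why the calls were lost was not tested. The medians stayed at -0.32 (thick ascending limb), -0.35 (endothelium), -0.72 (lymphocytes), 0.45 (erythroid), 1.07 (cell cycle) and 0.27 (cholesterol synthesis). Fry kept the first 2 and ended the others, with adjusted p of 0.455, 0.535, 0.966 and 0.393. With library weights the cell cycle list (0.104, adjusted p 0.267) and the cholesterol list (0.229, adjusted p 0.0571) were not called, and the cause was not tested. On log2(FPKM + 1), still called, the medians were 0.458 for cell cycle genes and -0.276 for lymphocyte genes, where the larger pseudocount shrinks changes of weakly expressed genes. Over the libraries left out, the median ran from 0.25 to 0.59 for erythroid genes, from 0.25 to 1.46 for cell cycle genes from 0.20 to 0.35 for cholesterol genes and from -1.24 to -0.54 for lymphocyte genes. Without CI-AKI replicate 3 the erythroid, cell cycle and cholesterol lists were not called with any scaling or tool, with medians of 0.54, 0.24 and 0.20 with median-of-ratios size factors, 0.54, 0.24 and 0.20 without scaling, and 0.55, 0.24 and 0.20 with DESeq2. The thick ascending limb, endothelium and lymphocyte lists were called with each library left out at the preset correlation, and with an estimated correlation no list was called with any library left out (smallest adjusted p from 0.325 to 0.789). None of the 6 lists called with all libraries turned its direction in any of these settings. Some other lists did, such as the glucocorticoid list, at -0.34 (called) without CI-AKI replicate 2 and 0.27 (not called) without CI-AKI replicate 3. Among named genes, 3043 values under an alternative stayed on their side of the threshold, 463 newly passed and 31 uncalled ones changed sign, and among other lists the numbers were 512, 30 and 56. Why DESeq2 called more genes than edgeR was not tested. The scalings moved the median log2 change of all genes from 0.005 to between 0 and 0.004, and with a library left out it lay between -0.012 and 0.009. At 20094729 to 23058144 counts per library, a count of 0 allows up to 0.13 to 0.149 CPM, and how depth limits the calls was not tested.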

Other observations

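The tests below that were chosen only after the result was seen are those of gene length, of the Mt-co1 level and of the correlations of CI-AKI replicate 3 with the controls. The test that took the place of these correlations was chosen after they had been seen, with its bound set before its own values were. With CI-AKI replicate 3 left out, 4 of 20 fatty acid genes rose and 2 fell in edgeR's quasi-likelihood test, and the list was not called (camera, adjusted p 0.597). The genes that rose were the pyruvate dehydrogenase kinase gene Pdk4 (log2 change 1.03, SE 0.20), the lipase inhibitor gene Angptl4 (1.61, SE 0.36), the thioesterase gene Acot2 (1.14, SE 0.16) and the carnitine transferase gene Cpt2 (0.82, SE 0.09). Acadm and Ehhadh, enzymes of mitochondrial and peroxisomal beta oxidation, fell by 0.49 (SE 0.12) and 0.74 (SE 0.17). Of 16 cell death genes 4 rose and 1 fell, with no call for the list (adjusted p 0.167), and Bid and Ripk3 were among those that rose (log2 changes 0.65 and 1.02), while the inflammasome gene Nlrp3 fell by 0.79. The matricellular genes Ctgf (1.56, SE 0.15) and Cyr61 (0.94, SE 0.08) also rose. In the same comparison the clock repressor gene Cry1 rose by 1.40 and Nr1d1, Dbp, Per3 and Nr1d2 fell by 3.13, 2.34, 1.33 and 1.13.

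Too few splits of the libraries exist (10) to give a share under 0.05, for the gene counts and the lists alike. For all genes the real value was 0 and the highest of the other splits 17, for protein-coding genes 0 and 14, and for lncRNA genes 0 and 0. For gene lists the real value was 6 and the highest other 10, and each of the other splits called at least 6. The number of lists called at the preset correlation therefore does not set the real grouping apart from the other splits. The 17 genes came from control replicate 2 with CI-AKI replicates 1 and 2 against the rest. This split is the real grouping with control replicate 2 and CI-AKI replicate 3 exchanged, and why it called more genes was not tested. With CI-AKI replicate 3 left out, the 10 splits of the other libraries are again too few, and the real value was 2324 genes and the highest other 2.

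CI-AKI replicate 3 stood apart from CI-AKI replicates 1 and 2. Gene length explained 0.32% of the variance of its log2 deviation from them, which argues against a length trend, and 1867 genes were still called without it among genes that overlap no other gene in the table, which argues against reads split between overlapping genes. A control kidney under the wrong label stays open: over about 2000 genes that differed most between CI-AKI replicates 1 and 2 and a pair of controls, it lay 0.05, 0.08 and 0.06 of the way toward the CI-AKI side, where control replicates 1, 2 and 3, each left out in turn, lay 0.01, 0.26 and -0.02 of the way, so that only control replicate 2 lay further than it. That test took the place of a first one on correlations, whose bound was set after they were seen and which argued against a wrong label, since its correlations with the controls (at most 0.9782) were below those between controls (at least 0.9823). The thick ascending limb median of CI-AKI replicate 3, at -0.37, was close to those of CI-AKI replicates 1 and 2. Its Rasd2 level of 4.47 CPM lay below the 18.0 to 22.9 of the controls. By these values the label may be right, but the list and the gene were both singled out in comparisons that included this library. Its cell cycle median of 1.77 lay outside both groups and speaks for neither label. On the second principal component, computed without group labels, CI-AKI replicate 3 lay at -35.5. The controls lay at 9.3 to 25.4 there and CI-AKI replicates 1 and 2 at -12.4 and 2.2. These positions separate the groups, with this library farthest from the controls, but were not used as a test of its label. An animal that responded little to the contrast medium predicts the same shares of the way and was not tested.

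Some genes encoded by mitochondrial DNA were counted in some libraries and almost absent from others, regardless of group. Mt-nd5 had 32595, 71606 and 12 counts in control replicates 1 to 3 and 55, 40 and 51832 in CI-AKI replicates 1 to 3, and Mt-co2 had 596, 1103 and 0 against 0, 0 and 761, while Mt-nd6 had 31709 in control replicate 3 and 23533 in CI-AKI replicate 3 and at most 368 elsewhere. The nuclear gene Kif5c, chosen after its values were seen, split the libraries as Mt-nd5 did but in reverse. It had 23, 33 and 1413 counts in control and 1418, 1107 and 41 in CI-AKI replicates 1 to 3, and it overlapped no other gene in the table. A difference in mitochondrial RNA content is argued against by Mt-co1, whose highest library was 1.54 times its lowest. Reads assigned to one or another of overlapping genes cannot be told apart from other sources, since 11 of 42 nuclear genes whose highest library was at least 20 times the lowest of the same group, not all of them off in that library, overlapped another gene, against 2443 of 13199 others (odds ratio 1.56, 95% interval 0.707 to 3.2, Fisher's exact test, two-sided p 0.23). The 42 genes were selected by that ratio alone and include Top2a, with 73, 49 and 1063 counts in CI-AKI replicates 1 to 3. The set thus mixes genes that are on or off with genes of other differences, and the test cannot decide about read assignment. No biological explanation other than mitochondrial RNA content was tested.

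Clock genes moved in opposite directions in CI-AKI replicates 1 and 2. Nr1d1 stood at 6.9 and 6.54 CPM there, at 52.3 in CI-AKI replicate 3 and at 85.5, 62.7 and 28.1 in control, and Cry1 at 47.7 and 43.8, at 13.1 and at 14.6, 16.1 and 21.4 CPM. For kidneys taken at another phase of the daily cycle, further genes that cycle in most organs were predicted to follow, and 1 of 4 did, while Tspan4, also planned, was not tested. Nfil3 was higher than in every control (22.3 and 27.4 against at most 13.9 CPM), but Usp2 (53.2 and 57.1 against 45.9 to 58.3 CPM), Wee1 and Lonrf3 were not lower than every control in both libraries. The prediction started from lower Dbp and higher Arntl, which these libraries showed. With only 4 further genes, the test cannot decide about a shift of phase, which stays open. An effect of the contrast medium or the injury on the clock, or of feeding during recovery, may also account for the movement of the clock genes and was not tested.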
